A study of Mus musculus with 20 samples.

How the data were processed

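The series holds 20 samples from a mouse C57BL/6 p30/p30 cell line grown with IL-3, of which 9 are RNA-seq libraries and 11 are ChIP-seq or input samples (4 C/EBPα, 2 MLL1 and 5 input), which were not analysed here. Per the labels' protocols, the RNA-seq samples were treated with DMSO, MI-463 or MI-503 at 0 h and 48 h and taken at 72 h, and RNA was extracted with an RNeasy Plus kit. The doses are not in the labels and MI-463 and MI-503 are used as code names, so they were compared only as treatments. Samples were grouped by the treatment in their titles, 3 per group, and each matched 1 column per the file headers.

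The deposited values are a signal in normalised read counts, made by the authors by dividing gene read counts by 1 size factor per library. Per the submitters' processing notes, FastQC, STAR, featureCounts, DESeq2, BWA, SAMtools, deepTools, MACS2, SICER and HOMER were used on the builds GRCm38 and mm10. The notes give no versions, roles or order, and the strand of counting is not stated, so overlapping and antisense genes cannot be separated here. Within each column all values (100%) were whole multiples of 1 step at a relative tolerance of 1e-06, so whole reads were recovered. For DMSO replicate 3 the step was 1.01, so close to 1 that its values are nearly whole as they stand. Recovered reads were 13,645,387, 14,182,169 and 14,441,888 in the DMSO libraries, 14,405,589, 13,882,881 and 14,452,138 with MI-463, and 15,803,683, 16,390,601 and 16,525,000 with MI-503. At that depth 1 read equals 0.895 to 1.07 normalised counts, and a gene at 0 in a library lies below a limit of 3 reads. The file held 24,454 Entrez genes, of which 24,376 were matched to GRCm38 symbols and 78 were not, and 8085 were at 0 in all libraries.

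The values were used as the authors normalised them. Genes with a mean of at least 10 over the 9 libraries were kept (11,366), and log2 of the value plus 1 was fitted with limma (3.58.1, in R 4.3.3) with 3 group means, 1 shared spread and an intensity trend. Comparisons were MI-463 against DMSO, MI-503 against DMSO and MI-503 against MI-463. A gene passed at a BH-adjusted p under 0.05, and intervals are 95%. The median SE of a log2 fold change was 0.119. Comparisons, groups, the 28 gene lists and the rule for naming genes were chosen before the data were examined. The tests of a lower share of mast-like and basophil-like cells and of the read total of MI-463 replicate 1 were chosen after the result was seen.

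By that rule, genes were named if they were among the 10 highest rises or deepest falls against DMSO (5 between the compounds) with a mean of at least 50 and groups that did not overlap, leaving out predicted and antisense genes. Kmt2a, Men1, Cebpa, Meis1 and Hoxa9 were named whatever their result, and so were up to 4 members per list with the smallest p. The text names a part of these, and also the 3 genes called in opposite directions. Osgin1 and Hmox1, named under other observations, were picked outside this rule because they were noticed in the data. Close paralogs, such as those of the Klk1b, Prl2c, Ly6 and Chil families, share reads and are uncertain.

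Gene lists were written from general knowledge, with 731 entries in 28 lists. They cover menin-MLL1 targets (26), MLL complex members and cofactors (27), C/EBP family and linked genes (21), primary granules (17), late granulocytes (36), monocytes and macrophages (36), stem and progenitor cells (27), mast cells and basophils (26), eosinophils (14), erythroid cells and megakaryocytes (29), lymphoid and dendritic cells (31), stroma (20), MHC class II (12), mitosis (30), DNA replication (35), MYC and ribosome biogenesis (35), cholesterol synthesis (26), LXR and lipid export (17), lysosomes (37), integrated stress response (32), endoplasmic reticulum stress (20), interferon-stimulated genes (31), p53 targets and cell death (24), glycolysis and hypoxia (28), oxidative phosphorylation (30), immediate early and heat shock genes (27) and cytokine signalling (24). The 13 mitochondrially encoded genes had no members among the file's identifiers and were not analysed here. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and, as a check, an estimated one, with BH adjustment over the 27 lists of a comparison. Some lists share members, for example Kit, Gata1 and Gata2.

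Both comparisons against DMSO used the same 3 DMSO libraries, so overlaps and correlations are given beside 100 simulations of data without effect and with shared controls. The pipeline was tested on simulated data of the same 9 libraries and 11,366 genes, with 50 changed genes per size for MI-463 against DMSO. It called 64% of the genes changed 1.5-fold, 84% of those changed 2-fold, 100% at 3-fold and 98% at 4-fold in the right direction, with 6 false calls among 179. A raised list was found by camera and 0 of 27 unchanged lists were called. The genes were simulated independently, so this does not show how camera behaves on lists of correlated genes. Far fewer genes were changed than were called in the data.

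Alternatives tried were other added constants, no or a stricter filter, TMM scaling, quantile normalisation, a fit of the 2 compared groups alone, limma without trend, sample weights, blocks of replicate number, a fold change of at least 2, each library left out in turn, edgeR (4.0.16) and DESeq2 (1.42.0) on recovered reads, and fry for lists. The edgeR quasi-likelihood test called 4478, 4816 and 86 genes and DESeq2 4471, 4816 and 258, against 4508, 4878 and 78 with limma, in the order of comparisons given above. One alternative, leaving out MI-463 replicate 1 and MI-503 replicate 3 together, and a list of 26 NRF2 targets were added after the results were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.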

Results

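RNA-seq values of 9 libraries from the p30/p30 myeloid-progenitor-derived mouse cell line were compared, 3 each with DMSO, MI-463 and MI-503. Of the variance, 65.3% lay on a first principal component that held the DMSO libraries at -40.7 to -38.4 and the libraries of both compounds at 16.5 to 23.2. MI-463 replicate 1 lay at 28.9 on the second component (14.3%), against -0.546 and 3.26 for replicates 2 and 3. MI-503 replicate 3 lay at 2.85 on it, against -14.6 and -16.6 for replicates 1 and 2. Log2 fold changes below are given ± SE of the limma fit and normalised read counts as mean ± SD, with n = 3 per group throughout. The labels do not say whether replicates were separate cultures, so each p-value measures only the spread between these samples, which may be technical.

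Kmt2a, which encodes the MLL1 histone methyltransferase (Entrez 214162, GRCm38 chromosome 9, 44803355 to 44881352), stood at 1952 ± 264 with DMSO, 2460.0 ± 245 with MI-463 and 2426 ± 268 with MI-503 (SD, n = 3). It rose slightly under MI-463 (log2 0.34 ± 0.12, adjusted p = 0.0322) and under MI-503 (log2 0.32 ± 0.12, adjusted p = 0.0402). Both calls hung on single libraries. Under MI-463 the adjusted p was 0.145 without DMSO replicate 1, 0.0926 without MI-463 replicate 1 and 0.0508 without MI-463 replicate 2. Under MI-503 it was 0.185 without DMSO replicate 1, 0.168 without MI-503 replicate 1 and 0.0941 without MI-503 replicate 2. Men1, which encodes menin (Entrez 17283, GRCm38 chromosome 19, 6334979 to 6340894), did not pass under MI-463 (log2 -0.20 ± 0.091, adjusted p = 0.101) or under MI-503 (log2 -0.057 ± 0.091, adjusted p = 0.647).

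Cebpa, the gene of the mutated transcription factor (Entrez 12606, GRCm38 chromosome 7, 35119293 to 35121928), fell from 6060.2 ± 487 with DMSO to 3786 ± 319.9 with MI-463 (log2 -0.68 ± 0.089, adjusted p = 4.61e-05) and 4605 ± 195 with MI-503 (log2 -0.39 ± 0.089, adjusted p = 0.00278, SD, n = 3). Meis1, a homeobox gene and a known target of menin and MLL1 (Entrez 17268, GRCm38 chromosome 11, 18880428 to 19019651), fell from 401 ± 12.2 to 289.5 ± 37.9 (log2 -0.48 ± 0.11, adjusted p = 0.00323) and 268 ± 8.17 (log2 -0.58 ± 0.11, adjusted p = 6.77e-04, SD, n = 3). Hoxa9, the partner of Meis1 in MLL-rearranged leukemia, had 1 read in DMSO replicate 3, 3 reads in MI-503 replicate 2 and 0 in the other 7 libraries, too few to test. Only 11 of the 26 listed menin-MLL1 target genes were expressed enough to test, and they moved both ways. Under MI-463, 3 rose, 6 fell and 2 did not pass (median log2 -0.32, camera adjusted p = 0.718, 4 and 6 when adjusted over the list alone). The mean of that list was 0.065, opposite in sign to its median and to the direction of the test. Under MI-503, 3 rose, 5 fell and 3 did not pass (median log2 -0.44, camera adjusted p = 0.356, 3 and 6 when adjusted over the list alone). Satb1, a chromatin organizer (2.08 ± 0.11 under MI-463, 2.03 ± 0.11 under MI-503), and the transcription factor gene Runx2 (1.28 ± 0.10 and 1.27 ± 0.10) rose under both compounds. Myb, which keeps progenitors immature (-0.76 ± 0.086 and -0.88 ± 0.086), fell under both.

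Among the members and cofactors of the MLL complexes, of 27 tested, 3 rose, 5 fell and 19 did not pass under MI-463 (median log2 -0.13, camera adjusted p = 0.301, 3 and 5 when adjusted over the list alone). The 5 that fell became 3 without DMSO replicate 2 and 3 without MI-463 replicate 3. Paxip1, a subunit of the MLL3 and MLL4 complexes (-0.49 ± 0.089 under MI-463, -0.54 ± 0.089 under MI-503), and Ash2l, a core subunit of all of them (-0.37 ± 0.083 and -0.35 ± 0.083), fell under both compounds. Under MI-503, of 27 tested, 1 rose, 6 fell and 20 did not pass (median log2 -0.074, camera adjusted p = 0.348, 0 and 5 when adjusted over the list alone). The 6 that fell became 3 without MI-503 replicate 2. The 1 that rose, Kmt2a, became 0 without DMSO replicate 1, MI-503 replicate 1 or MI-503 replicate 2, 2 without DMSO replicate 3 or MI-503 replicate 3, and 3 without MI-463 replicate 1.

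**Figure D1:**
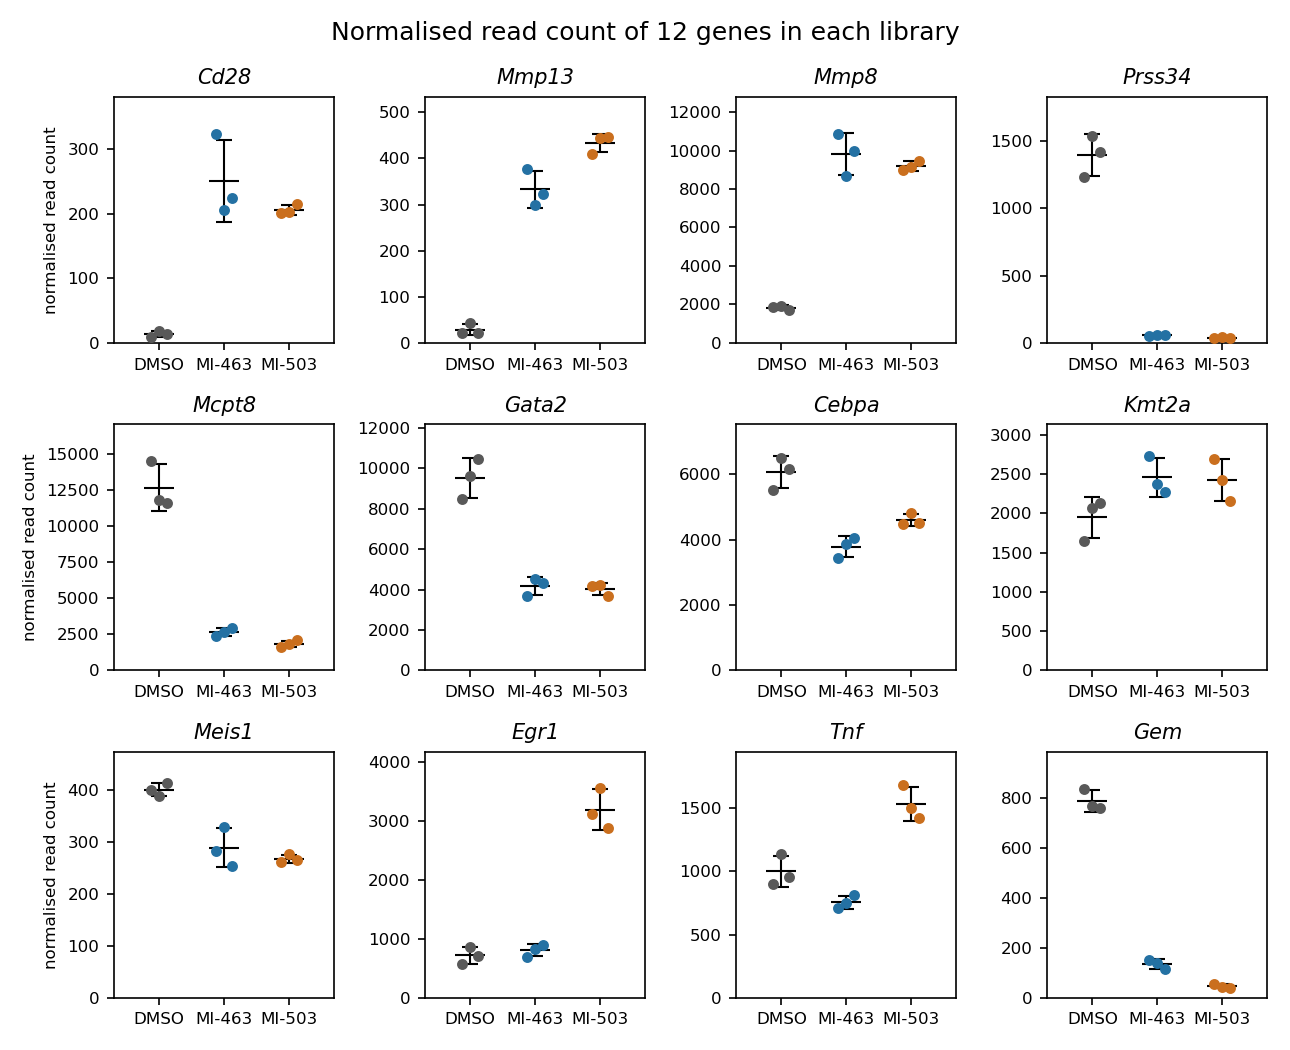
Normalised read count (vertical axis) of 12 genes in each library, by treatment (horizontal axis), with mean and SD of 3 libraries. Prss34 stood at 1398 ± 154 with DMSO and 39.8 ± 3.81 with MI-503, and Egr1 at 806 ± 104 with MI-463 and 3183 ± 347 with MI-503.

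MI-463 moved a large part of the expressed genes. Of 11,366 genes tested with limma, 4508 (39.7%) passed at a BH-adjusted p under 0.05, 2368 of them higher and 2140 lower than with DMSO. At a fold change of at least 2 the numbers were 601 higher and 187 lower. Among genes with a mean of at least 50, the highest rises were those of Cd28 and Mmp13. Cd28, a costimulatory receptor of T cells (Entrez 12487, GRCm38 chromosome 1, 60746388 to 60773359), went from 13.4 ± 4.64 to 251 ± 63.4 (SD, n = 3, log2 4.15 ± 0.23, adjusted p = 1.75e-08). Mmp13, a collagenase (Entrez 17386, GRCm38 chromosome 9, 7272514 to 7283333), went from 29.1 ± 12.7 to 333 ± 40.5 (SD, n = 3, log2 3.55 ± 0.21, adjusted p = 4.11e-08). Slc40a1, the iron exporter ferroportin (3.45 ± 0.30), Ptgis, prostacyclin synthase (3.07 ± 0.20), and the netrin receptor gene Unc5b (3.02 ± 0.38) rose too. Klk1b1 (3.12 ± 0.11) and Klk1b11 (2.92 ± 0.14), of the kallikrein family, also rose, but their close paralogs make the assignment of reads uncertain. Every gene named against DMSO that passed, except Kmt2a and Elane, kept its call and direction in each setting tried that has no fold threshold. The groups did not overlap in 5561 genes (48.9%), where chance gives 10%.

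The deepest fall under MI-463 was that of Prss34, a serine protease of mast cells and basophils (Entrez 328780, GRCm38 chromosome 17, 25298394 to 25300168), from 1398 ± 154 to 56.3 ± 6.39 (SD, n = 3, log2 -4.61 ± 0.14, adjusted p = 1.80e-10). Mcpt8, the basophil protease (Entrez 17231, GRCm38 chromosome 14, 56082163 to 56085499), fell from 12691 ± 1623 to 2675 ± 267 (log2 -2.24 ± 0.11, adjusted p = 9.46e-09). Hdc, which makes histamine (-2.18 ± 0.12), Frzb, a secreted WNT antagonist (-3.01 ± 0.22), Gem, a small GTPase (-2.53 ± 0.15), and the sialomucin gene Podxl (-2.18 ± 0.090) fell as well. Of the mast cell and basophil genes, of 22 tested, 2 rose, 17 fell and 3 did not pass (median log2 -0.82, camera adjusted p = 1.76e-07, adjusted p = 0.0143 with an estimated correlation, 2 and 17 when adjusted over the list alone). Gata2, a transcription factor of stem cells and mast cells, fell (log2 -1.19 ± 0.10, adjusted p = 9.49e-07), and Kit, the stem cell factor receptor, rose (log2 1.08 ± 0.070, adjusted p = 7.35e-08).

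Late granulocyte genes rose under MI-463. Here of 35 tested, 26 rose, 1 fell and 8 did not pass (median log2 0.67, camera adjusted p = 1.90e-11, adjusted p = 0.00650 with an estimated correlation, 26 and 1 when adjusted over the list alone). Mmp8, a collagenase of secondary granules, rose from 1839 ± 110.0 to 9820.2 ± 1104 (SD, n = 3, log2 2.41 ± 0.090, adjusted p = 6.85e-10). Ifitm6 rose by 2.55 ± 0.097, the lectin gene Clec4d by 2.25 ± 0.10 and Ltf, lactoferrin, by 1.71 ± 0.097. Primary granule genes went both ways: of 17 tested, 5 rose, 8 fell and 4 did not pass (median log2 -0.19, camera adjusted p = 0.307, 5 and 8 when adjusted over the list alone). Mpo, myeloperoxidase, fell (log2 -1.12 ± 0.12, adjusted p = 8.83e-06), while Lyz2, lysozyme, rose (log2 1.67 ± 0.11, adjusted p = 6.75e-08). Not every gene of that list encodes a granule protein (Igfbp4 does not), so its counts are not those of granule proteins alone. Monocyte and macrophage genes rose, and of 29 tested, 23 rose, 1 fell and 5 did not pass (median log2 1.03, camera adjusted p = 7.06e-13, adjusted p = 0.0243 with an estimated correlation, 24 and 1 when adjusted over the list alone). Gpnmb, a glycoprotein of phagocytes (2.81 ± 0.12), the transcription factor gene Maf (2.34 ± 0.13), Mpeg1, perforin-2 (1.92 ± 0.089), and F13a1, a coagulation factor subunit (1.61 ± 0.088), were among them. Csf1r, the M-CSF receptor, rose (log2 1.15 ± 0.11, adjusted p = 2.47e-06). The C/EBP family and linked genes were mixed, since of 20 tested, 10 rose, 3 fell and 7 did not pass (median log2 0.34, camera adjusted p = 0.132, 10 and 3 when adjusted over the list alone). With an estimated correlation their camera adjusted p was 0.565. They passed when MI-463 replicate 1 and MI-503 replicate 3 were both left out (camera adjusted p = 0.0442), a setting added after the data were seen.

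Among stem and progenitor genes, of 19 tested, 5 rose, 9 fell and 5 did not pass under MI-463 (median log2 -0.27, camera adjusted p = 0.280, 6 and 10 when adjusted over the list alone). Their mean was 0.020, opposite in sign to the median and the test. Ly6a, known as Sca-1, rose (2.66 ± 0.094), with a close paralog that limits the assignment, and Cd93 rose (1.90 ± 0.069). Eosinophil genes split (of 8 tested, 3 rose, 4 fell and 1 did not pass, median log2 -0.043, camera adjusted p = 0.814, 3 and 4 when adjusted over the list alone). Siglecf rose (0.71 ± 0.077) and Il1rl1, the IL-33 receptor, fell (-0.84 ± 0.090). Erythroid and megakaryocyte genes split as well (of 10 tested, 4 rose, 4 fell and 2 did not pass, median log2 -0.071, camera adjusted p = 0.943, 4 and 4 when adjusted over the list alone), and their mean was 0.069. The integrin gene Itgb3 (1.31 ± 0.091) rose and Gata1 (-1.17 ± 0.14) fell. Of the lymphoid and dendritic cell genes, of 8 tested, 4 rose, 1 fell and 3 did not pass (median log2 0.62, camera adjusted p = 0.0259, adjusted p = 0.1203 with an estimated correlation, 5 and 1 when adjusted over the list alone). Camera did not pass without a filter (adjusted p = 0.453) or with a filter at a mean of 50 (0.169). The 1 that fell became 0 without DMSO replicate 3, MI-463 replicate 1 or MI-463 replicate 3, while Lef1 (1.94 ± 0.13) and Il7r (1.70 ± 0.16) rose. Stromal genes gave a median of -0.10, a mean of 0.21 and a test upward (of 7 tested, 3 rose, 1 fell and 3 did not pass, median log2 -0.10, camera adjusted p = 0.804, 3 and 1 when adjusted over the list alone). MHC class II genes rose by count but not once correlation was estimated (of 11 tested, 9 rose, 0 fell and 2 did not pass, median log2 0.50, camera adjusted p = 4.89e-04, adjusted p = 0.323 with an estimated correlation, 9 and 0 when adjusted over the list alone). Ctss, cathepsin S, rose (1.81 ± 0.13).

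Of the DNA replication genes, of 35 tested, 0 rose, 32 fell and 3 did not pass under MI-463 (median log2 -0.53, camera adjusted p = 5.23e-13, adjusted p = 0.0143 with an estimated correlation, 0 and 33 when adjusted over the list alone). Chaf1b, a chromatin assembly subunit (-1.05 ± 0.098), Mcm4, of the replicative helicase (-0.75 ± 0.071), and Tyms, thymidylate synthase (-0.76 ± 0.082), were among them. For MYC and ribosome biogenesis genes, of 35 tested, 0 rose, 29 fell and 6 did not pass (median log2 -0.52, camera adjusted p = 9.80e-12, adjusted p = 0.00650 with an estimated correlation, 0 and 30 when adjusted over the list alone). Srm, spermidine synthase (-0.88 ± 0.11), and Mrto4, a ribosome assembly factor (-0.76 ± 0.089), both fell. Among mitotic genes, of 30 tested, 1 rose, 9 fell and 20 did not pass (median log2 -0.19, camera adjusted p = 0.0138, adjusted p = 0.330 with an estimated correlation, 1 and 8 when adjusted over the list alone). The 9 that fell became 15 without MI-463 replicate 1, the 1 that rose became 0 without MI-463 replicate 2, and without that library the camera adjusted p was 0.0587. Aurkb, a mitotic kinase, fell (-0.43 ± 0.086). Oxidative phosphorylation genes passed camera but not with an estimated correlation (of 30 tested, 0 rose, 11 fell and 19 did not pass, median log2 -0.23, camera adjusted p = 0.00300, adjusted p = 0.330 with an estimated correlation, 0 and 10 when adjusted over the list alone). Their 11 falls became 6 without DMSO replicate 1, 7 without DMSO replicate 3, 6 without MI-463 replicate 2 and 7 without MI-463 replicate 3. Idh3a, of the citric acid cycle, fell (-0.46 ± 0.096).

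Cholesterol synthesis genes rose under MI-463, and of 25 tested, 22 rose, 0 fell and 3 did not pass (median log2 0.72, camera adjusted p = 8.21e-11, adjusted p = 0.0143 with an estimated correlation, 23 and 0 when adjusted over the list alone). Hmgcs1, HMG-CoA synthase, went from 1892 ± 44.5 to 4192 ± 342 (SD, n = 3, log2 1.14 ± 0.085, adjusted p = 2.74e-07), and Cyp51 (1.07 ± 0.10) and Fdft1, squalene synthase (0.81 ± 0.077), rose with it. LXR and lipid export genes split: of 15 tested, 4 rose, 5 fell and 6 did not pass (median log2 -0.024, camera adjusted p = 0.814, 5 and 5 when adjusted over the list alone), with a mean of 0.093 against a negative median. The 5 that fell became 2 without DMSO replicate 3. Plin2, which coats lipid droplets (1.04 ± 0.11), rose and Abcg1, a sterol exporter (-0.50 ± 0.092), fell. Lysosome genes rose by count, and camera lost the call with an estimated correlation (of 36 tested, 28 rose, 2 fell and 6 did not pass, median log2 0.56, camera adjusted p = 2.36e-10, adjusted p = 0.0970 with an estimated correlation, 29 and 2 when adjusted over the list alone). Psap, prosaposin (1.76 ± 0.13), and the sulfatase gene Gns (1.14 ± 0.080) rose.

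Interferon-stimulated genes rose under MI-463, since of 26 tested, 21 rose, 0 fell and 5 did not pass (median log2 1.10, camera adjusted p = 3.40e-12, adjusted p = 0.0143 with an estimated correlation, 21 and 0 when adjusted over the list alone). Rsad2, viperin, went from 10.7 ± 2.93 to 104 ± 9.08 (SD, n = 3, log2 3.20 ± 0.21, adjusted p = 9.33e-08), and Irf7, a transcription factor of the interferon response (1.95 ± 0.10), and Ddx58, the RNA sensor RIG-I (1.13 ± 0.091), rose. Among p53 targets and cell death genes, of 22 tested, 14 rose, 3 fell and 5 did not pass (median log2 0.51, camera adjusted p = 0.00468, adjusted p = 0.0480 with an estimated correlation, 14 and 3 when adjusted over the list alone). The proapoptotic genes Bcl2l11 (1.09 ± 0.078) and Pmaip1 (1.28 ± 0.13) rose. Integrated stress response genes fell short of the threshold (of 27 tested, 11 rose, 5 fell and 11 did not pass, median log2 0.19, camera adjusted p = 0.0520, 11 and 6 when adjusted over the list alone). With an estimated correlation the camera adjusted p of that list was 0.526. Without DMSO replicate 3, MI-463 replicate 1 or MI-503 replicate 3 that list passed (camera adjusted p = 0.0182, 0.0213 and 0.0459), and its 5 falls became 3 without DMSO replicate 3. It also passed without a filter (camera adjusted p = 0.0222), with quantile normalisation (0.0398), with sample weights (0.0231) and in the added setting without both MI-463 replicate 1 and MI-503 replicate 3 (0.0176). Slc7a11, the cystine transporter (2.51 ± 0.094), and Ddit3, the stress factor CHOP (1.37 ± 0.12), rose.

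Endoplasmic reticulum stress genes also fell short under MI-463 (of 20 tested, 4 rose, 10 fell and 6 did not pass, median log2 -0.23, camera adjusted p = 0.0520, 4 and 10 when adjusted over the list alone). With an estimated correlation their camera adjusted p was 0.133. They passed without DMSO replicate 3, MI-463 replicate 1 or MI-503 replicate 3 (camera adjusted p = 0.0287, 0.0434 and 0.0483), without a filter (0.0282), with sample weights (0.0356) and in the added setting without both MI-463 replicate 1 and MI-503 replicate 3 (0.0414). Their 4 rises became 2 without DMSO replicate 1, DMSO replicate 3 or MI-463 replicate 1. Calr, the chaperone calreticulin, fell (log2 -0.73 ± 0.091, adjusted p = 3.26e-05). Immediate early and heat shock genes were mixed (of 25 tested, 9 rose, 7 fell and 9 did not pass, median log2 0.17, camera adjusted p = 0.220, 9 and 7 when adjusted over the list alone). Klf6 (1.90 ± 0.081), Jun (2.01 ± 0.12) and Dusp1 (1.69 ± 0.11), all induced early after stimulation, rose. For glycolysis and hypoxia genes the median was -0.005, the mean 0.041 and the test downward (of 26 tested, 6 rose, 7 fell and 13 did not pass, median log2 -0.005, camera adjusted p = 0.904, 6 and 7 when adjusted over the list alone). Ndrg1 (1.12 ± 0.096) and Vegfa (0.99 ± 0.085), both induced by hypoxia, rose, and Tpi1, of glycolysis (-0.55 ± 0.086), fell. Cytokine signalling genes were mixed (of 22 tested, 4 rose, 6 fell and 12 did not pass, median log2 -0.064, camera adjusted p = 0.477, 5 and 6 when adjusted over the list alone). Their 4 rises became 8 without MI-463 replicate 1. Etv5, a target of ERK signalling (-1.13 ± 0.089), and Lif, a cytokine gene (-1.03 ± 0.089), fell.

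**Figure D2:**
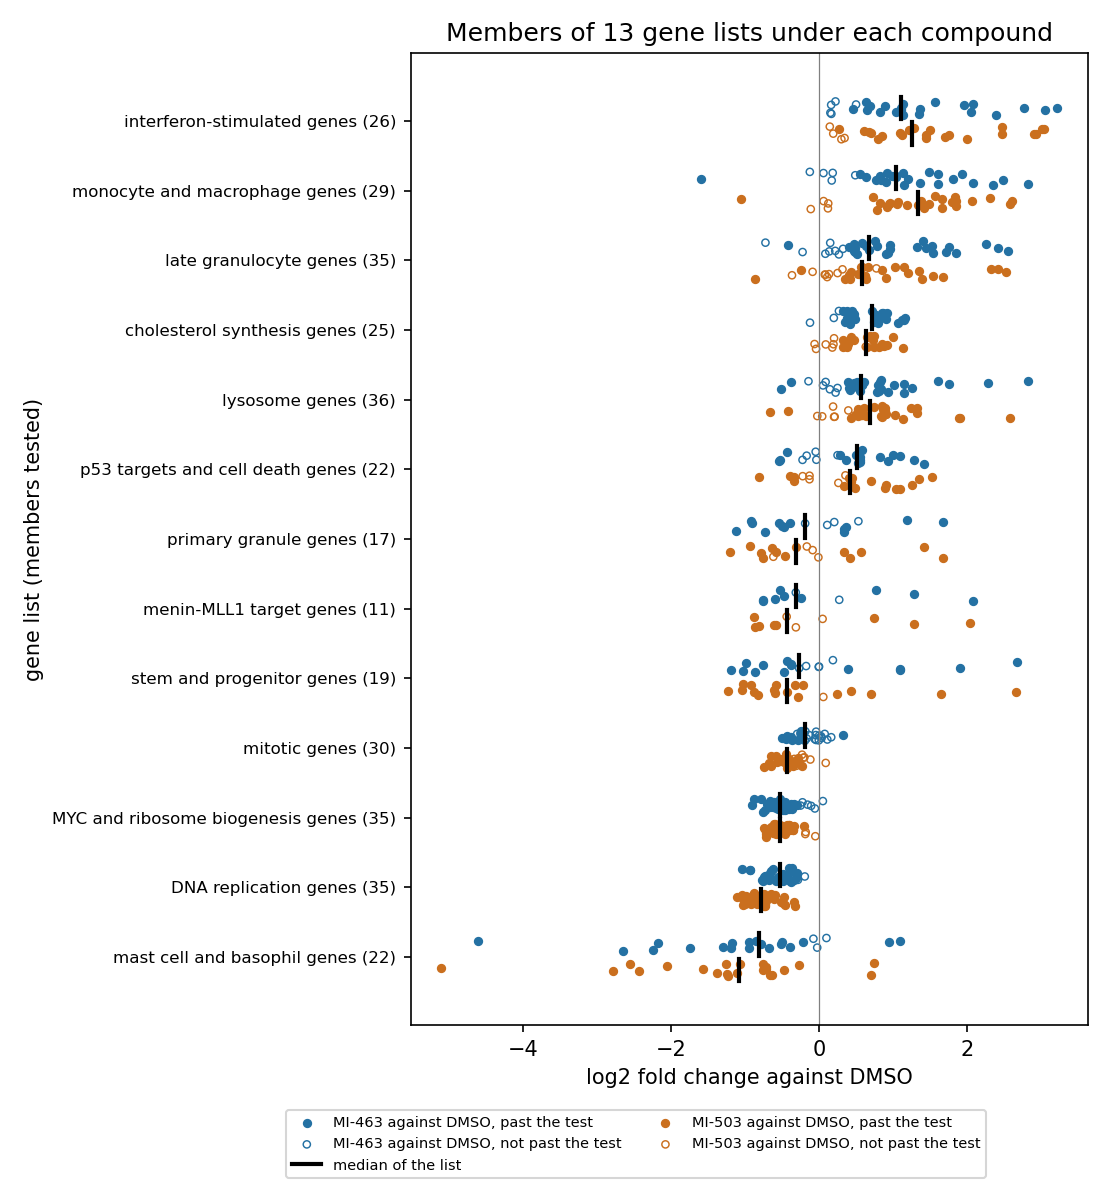
Log2 fold change against DMSO (horizontal axis) of each tested member of 13 gene lists (vertical axis), for MI-463 and MI-503, 3 libraries per group. Interferon-stimulated genes had medians of 1.10 and 1.25, and mast cell and basophil genes of -0.82 and -1.09.

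With MI-503, 4878 of the 11,366 genes (42.9%) passed limma at a BH-adjusted p under 0.05, 2489 higher and 2389 lower than with DMSO. At a fold change of at least 2 there were 650 higher and 241 lower. Mmp13 rose from 29.1 ± 12.7 to 433 ± 19.8 (SD, n = 3, log2 3.93 ± 0.21, adjusted p = 1.30e-08) and Cd28 to 206 ± 7.43 (log2 3.90 ± 0.23, adjusted p = 2.63e-08). Ptgis (3.72 ± 0.20) and Slc40a1 (3.57 ± 0.30) rose as they had with MI-463, and the neutrophil chemokine genes Cxcl2 (3.01 ± 0.10) and Cxcl3 (3.08 ± 0.20) were among the 10 highest rises of genes with a mean of at least 50. Among genes with a mean of at least 50, the deepest falls were those of Prss34, to 39.8 ± 3.81 (log2 -5.10 ± 0.14, adjusted p = 4.67e-11), Gem, from 786 ± 42.5 to 46.7 ± 8.80 (log2 -4.06 ± 0.15, adjusted p = 4.69e-10), and Podxl (log2 -3.03 ± 0.090, adjusted p = 1.18e-10). Ddah1, which breaks down methylated arginines (-2.54 ± 0.094), the growth factor gene Fgf3 (-2.58 ± 0.20) and Gp1ba, a platelet adhesion receptor (-2.57 ± 0.15), fell too. The groups did not overlap in 6041 genes (53.1%), where chance gives 10%.

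Mast cell and basophil genes fell under MI-503, and of 22 tested, 2 rose, 20 fell and 0 did not pass (median log2 -1.09, camera adjusted p = 7.20e-10, adjusted p = 0.00861 with an estimated correlation, 2 and 20 when adjusted over the list alone). Mcpt8 went from 12691 ± 1623 to 1842 ± 227 (SD, n = 3, log2 -2.78 ± 0.11, adjusted p = 1.07e-09), and Hdc (-2.44 ± 0.12), the chymase gene Cma1 (-1.24 ± 0.081) and Gata2 (-1.23 ± 0.10) fell. Of the late granulocyte genes, of 35 tested, 24 rose, 2 fell and 9 did not pass (median log2 0.58, camera adjusted p = 1.22e-08, adjusted p = 0.00861 with an estimated correlation, 25 and 2 when adjusted over the list alone). The 2 that fell became 1 without DMSO replicate 2 or 3, without MI-463 replicate 3 and without any 1 of the MI-503 libraries. Mmp8 (2.32 ± 0.090), Ifitm6 (2.52 ± 0.097) and Itgam, the integrin CD11b (1.53 ± 0.076), rose. Monocyte and macrophage genes rose (of 29 tested, 24 rose, 1 fell and 4 did not pass, median log2 1.34, camera adjusted p = 7.96e-14, adjusted p = 0.0239 with an estimated correlation, 24 and 1 when adjusted over the list alone). Their median was higher than with MI-463. Compared directly, their median difference between the compounds was only 0.079 (camera adjusted p = 0.00734, adjusted p = 0.328 with an estimated correlation). F13a1 (2.06 ± 0.088), Maf (2.60 ± 0.13), Gpnmb (2.57 ± 0.12) and Csf1r (1.37 ± 0.11) were among the genes that rose. Primary granule genes again went both ways (of 17 tested, 5 rose, 8 fell and 4 did not pass, median log2 -0.31, camera adjusted p = 0.158, 5 and 9 when adjusted over the list alone). Lyz2 rose (1.67 ± 0.11) and Igfbp4, a list member that encodes no granule protein, fell (-0.93 ± 0.078).

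C/EBP family and linked genes did not pass under MI-503 (of 20 tested, 10 rose, 6 fell and 4 did not pass, median log2 0.41, camera adjusted p = 0.0639, 10 and 6 when adjusted over the list alone). With an estimated correlation their camera adjusted p was 0.462. They passed without DMSO replicate 2, MI-503 replicate 1 or a filter (camera adjusted p = 0.0458, 0.0435 and 0.0437), and in the added setting without both MI-463 replicate 1 and MI-503 replicate 3 (0.0388). Their 6 falls became 3 without DMSO replicate 3 or MI-503 replicate 2. Cebpe, which drives late granulocyte maturation, rose (log2 0.87 ± 0.11, adjusted p = 3.13e-05). Stem and progenitor genes passed downward, though not with an estimated correlation (of 19 tested, 5 rose, 13 fell and 1 did not pass, median log2 -0.43, camera adjusted p = 0.0296, adjusted p = 0.0989 with an estimated correlation, 5 and 13 when adjusted over the list alone). Without a filter they did not pass (camera adjusted p = 0.0516). Ly6a (2.66 ± 0.094) and Cd93 (1.65 ± 0.069) rose. Eosinophil genes split (of 8 tested, 3 rose, 4 fell and 1 did not pass, median log2 -0.47, camera adjusted p = 0.687, 3 and 4 when adjusted over the list alone). Their 4 falls became 2 without MI-503 replicate 1. Il1rl1 fell (-1.52 ± 0.090). Erythroid and megakaryocyte genes had a mean of 0.15 against a negative median and test (of 10 tested, 4 rose, 5 fell and 1 did not pass, median log2 -0.22, camera adjusted p = 0.941, 4 and 5 when adjusted over the list alone). Ppbp, a platelet chemokine gene, rose (2.66 ± 0.16) and Gata1 fell (-1.38 ± 0.14).

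Of the lymphoid and dendritic cell genes, of 8 tested, 4 rose, 1 fell and 3 did not pass under MI-503 (median log2 0.53, camera adjusted p = 0.0387, adjusted p = 0.126 with an estimated correlation, 5 and 1 when adjusted over the list alone). Camera did not pass without MI-463 replicate 1 (adjusted p = 0.0522), without MI-503 replicate 2 (0.0631), without a filter (0.261), with a filter at a mean of 50 (0.114) or with quantile normalisation (0.0528). The 1 fall became 0 without DMSO replicate 3 or MI-503 replicate 1. Lef1, a transcription factor of WNT signalling, rose (log2 2.36 ± 0.13, adjusted p = 1.97e-08). Stromal genes did not pass as a list (of 7 tested, 3 rose, 0 fell and 4 did not pass, median log2 0.17, camera adjusted p = 0.514, 3 and 0 when adjusted over the list alone). Their 3 rises became 1 without DMSO replicate 1, DMSO replicate 3, MI-503 replicate 1 or MI-503 replicate 2. Vim, vimentin, rose (log2 0.48 ± 0.087, adjusted p = 5.33e-04). MHC class II genes passed camera but not with an estimated correlation (of 11 tested, 8 rose, 0 fell and 3 did not pass, median log2 0.42, camera adjusted p = 2.77e-04, adjusted p = 0.234 with an estimated correlation, 9 and 0 when adjusted over the list alone). Both H2-DMa (0.86 ± 0.12) and H2-Ob (0.90 ± 0.12), which act in antigen loading, rose.

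All 35 DNA replication genes fell under MI-503 (median log2 -0.78, camera adjusted p = 5.07e-17, adjusted p = 0.00861 with an estimated correlation, 0 and 35 when adjusted over the list alone). Tyms (-1.05 ± 0.082), Rrm2, of ribonucleotide reductase (-1.01 ± 0.081), and Mcm4 (-0.94 ± 0.071) are examples. Of the mitotic genes, of 30 tested, 0 rose, 23 fell and 7 did not pass (median log2 -0.44, camera adjusted p = 7.95e-08, adjusted p = 0.0588 with an estimated correlation, 0 and 24 when adjusted over the list alone). Top2a, topoisomerase II (-0.74 ± 0.11), and Cdk1 (-0.57 ± 0.094) fell. For MYC and ribosome biogenesis genes, of 35 tested, 0 rose, 32 fell and 3 did not pass (median log2 -0.53, camera adjusted p = 1.89e-11, adjusted p = 0.00729 with an estimated correlation, 0 and 32 when adjusted over the list alone). Nolc1 (-0.65 ± 0.079), Dkc1, dyskerin (-0.73 ± 0.095), and Polr1b, of RNA polymerase I (-0.74 ± 0.097), fell. Oxidative phosphorylation genes passed camera but not with an estimated correlation (of 30 tested, 0 rose, 10 fell and 20 did not pass, median log2 -0.21, camera adjusted p = 0.00251, adjusted p = 0.263 with an estimated correlation, 0 and 10 when adjusted over the list alone). Ndufs1, of complex I, fell (-0.72 ± 0.094).

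Cholesterol synthesis genes rose under MI-503, and of 25 tested, 18 rose, 0 fell and 7 did not pass (median log2 0.63, camera adjusted p = 4.78e-08, adjusted p = 0.0273 with an estimated correlation, 19 and 0 when adjusted over the list alone). Mvd, of the mevalonate pathway (0.998 ± 0.087), and Hmgcs1 (0.92 ± 0.085) rose. LXR and lipid export genes split (of 15 tested, 4 rose, 5 fell and 6 did not pass, median log2 -0.18, camera adjusted p = 0.577, 4 and 6 when adjusted over the list alone). Abcg1 fell (-1.13 ± 0.092) and Plin2 rose (1.09 ± 0.11). Lysosome genes passed camera but not with an estimated correlation (of 36 tested, 28 rose, 2 fell and 6 did not pass, median log2 0.69, camera adjusted p = 6.04e-11, adjusted p = 0.0760 with an estimated correlation, 31 and 2 when adjusted over the list alone). Npc1, which moves cholesterol out of lysosomes, rose (0.86 ± 0.085). Interferon-stimulated genes rose, and of 26 tested, 22 rose, 0 fell and 4 did not pass (median log2 1.25, camera adjusted p = 6.04e-13, adjusted p = 0.00976 with an estimated correlation, 22 and 0 when adjusted over the list alone). Irf7 went from 138 ± 9.58 to 765 ± 13.1 (SD, n = 3, log2 2.46 ± 0.10, adjusted p = 1.07e-09), and Ddx58 (1.28 ± 0.091) and Xaf1 (1.99992 ± 0.16) rose. Of p53 targets and cell death genes, of 22 tested, 13 rose, 4 fell and 5 did not pass (median log2 0.41, camera adjusted p = 0.00576, adjusted p = 0.0578 with an estimated correlation, 14 and 4 when adjusted over the list alone). Their 4 falls became 2 without DMSO replicate 1 or MI-503 replicate 2. Bcl2, which protects from cell death, fell (-0.81 ± 0.085), while Btg2 (1.52 ± 0.11), Bcl2l11 (1.04 ± 0.078) and Pmaip1 (1.34 ± 0.13) rose.

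Integrated stress response genes passed camera under MI-503 but not with an estimated correlation (of 27 tested, 14 rose, 4 fell and 9 did not pass, median log2 0.41, camera adjusted p = 0.00180, adjusted p = 0.234 with an estimated correlation, 14 and 4 when adjusted over the list alone). Their 4 falls became 1 without DMSO replicate 1, 0 without DMSO replicate 3, 2 without MI-463 replicate 3, 2 without MI-503 replicate 1, 0 without MI-503 replicate 2 and 1 without MI-503 replicate 3. Trib3, a pseudokinase induced by ATF4 (1.66 ± 0.12), Ddit4 (1.82 ± 0.10), Ddit3 (1.39 ± 0.12) and Slc7a11 (2.45 ± 0.094) rose. Endoplasmic reticulum stress genes passed narrowly downward (of 20 tested, 2 rose, 10 fell and 8 did not pass, median log2 -0.23, camera adjusted p = 0.0471, adjusted p = 0.125 with an estimated correlation, 2 and 10 when adjusted over the list alone). That call was lost without DMSO replicate 1 (camera adjusted p = 0.0545), DMSO replicate 2 (0.0558), MI-463 replicate 1 (0.0546), MI-463 replicate 3 (0.0518), MI-503 replicate 1 (0.0510) or MI-503 replicate 2 (0.0634). It was also lost with a filter at a mean of 50 (0.0663), quantile normalisation (0.0555) and limma without trend (0.0580, all camera adjusted p). Calr fell (-0.79 ± 0.091) and Herpud1, of protein degradation at the reticulum, rose (0.58 ± 0.087).

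Immediate early and heat shock genes passed camera under MI-503 but not with an estimated correlation (of 25 tested, 13 rose, 6 fell and 6 did not pass, median log2 0.54, camera adjusted p = 0.00196, adjusted p = 0.161 with an estimated correlation, 15 and 6 when adjusted over the list alone). Dusp1 (2.14 ± 0.11), Jun (2.26 ± 0.12) and Zfp36, which destabilizes cytokine transcripts (2.10 ± 0.13), rose. Glycolysis and hypoxia genes did not pass as a list (of 26 tested, 7 rose, 6 fell and 13 did not pass, median log2 0.054, camera adjusted p = 0.687, 7 and 6 when adjusted over the list alone). Their 7 rises became 4 without MI-503 replicate 2. Vegfa (1.20 ± 0.085) rose and Pfkfb3, which promotes glycolysis (-0.46 ± 0.074), fell. Cytokine signalling genes had a mean of -0.089 against a positive median and test (of 22 tested, 10 rose, 6 fell and 6 did not pass, median log2 0.17, camera adjusted p = 0.935, 10 and 7 when adjusted over the list alone). Their 10 rises became 6 without DMSO replicate 1 or MI-503 replicate 2. Etv5 (-1.64 ± 0.089) and Etv4 (-3.63 ± 0.29), targets of ERK signalling, fell, and the repressor gene Bcl6 rose (1.85 ± 0.12).

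The responses to both compounds ran in parallel across genes. In the same direction, 3557 genes passed under both, 1922 higher and 1635 lower. Independent calls would give 519 and 449.8. Data simulated without effect but with shared DMSO libraries gave 0.01 on average (highest 1 of 100 simulations). In data without effect BH adjustment leaves few genes called in either comparison, so that value was bound to be small. It does not measure what the shared libraries add to the overlap. Signs matched in 83.8% of genes, against 66.7% simulated, and the log2 fold changes correlated at r = 0.915, against 0.499 simulated, across genes that are not independent replicates. Their covariance was 0.294, against 0.0123 simulated. Part of the excess over independent calls may come from the shared DMSO libraries, since 3 of them cannot be split into groups of 2. By mean change, among genes with a mean of at least 50, the highest rises were those of Cd28, Mmp13, Slc40a1, Ptgis and Klk1b1, and the deepest falls those of Prss34, Gem, Frzb, Podxl and Mcpt8. Opposite directions were called for 3 genes: Tnf, Elane and Tspoap1. Of the other calls, 948 passed with MI-463 alone and 1318 with MI-503 alone, which does not show that those genes differed between the compounds.

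**Figure D3:**
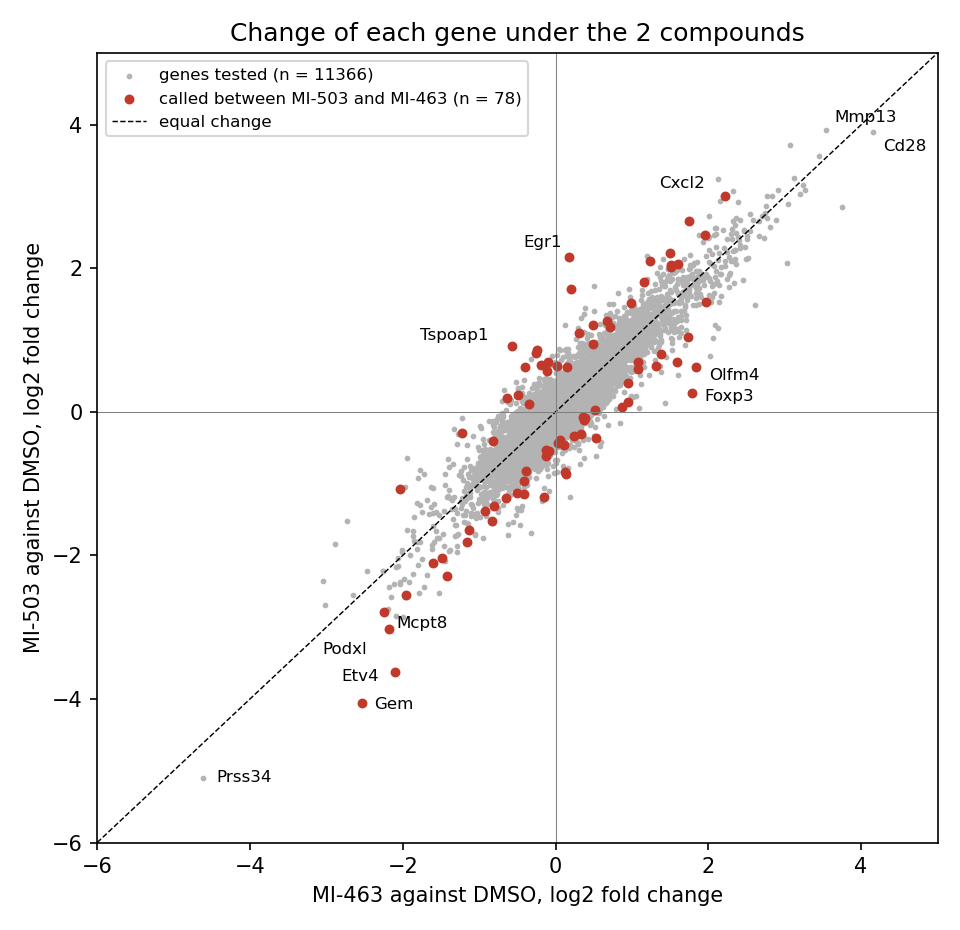
Log2 fold change under MI-463 (horizontal axis) and MI-503 (vertical axis), each against the same 3 DMSO libraries, for 11,366 genes. The 78 genes called between MI-503 and MI-463 are red, and Egr1 lies 1.98 above the line of equal change.

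Between MI-503 and MI-463, 78 genes passed limma at a BH-adjusted p under 0.05, 32 higher and 46 lower with MI-503, and 12 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1798 genes, edgeR called 86 and DESeq2 called 258. Leaving out 1 library gave 16 without MI-503 replicate 2, 26 without MI-503 replicate 1, 33 without MI-463 replicate 2 and 50 without MI-463 replicate 1. Egr1, an early growth response factor (Entrez 13653, GRCm38 chromosome 18, 34861207 to 34864956), was at 806 ± 104 with MI-463 and 3183 ± 347 with MI-503 (SD, n = 3, log2 1.98 ± 0.14, adjusted p = 1.95e-05, 95% interval 1.68 to 2.28). Ier2, another immediate early gene, was also higher with MI-503 (log2 1.07 ± 0.11, adjusted p = 4.17e-04, 95% interval 0.83 to 1.32). Tspoap1, a binding partner of the TSPO protein (Entrez 207777, GRCm38 chromosome 11, 87758194 to 87785928), was higher by 1.49 ± 0.13 (95% interval 1.22 to 1.76, adjusted p = 9.77e-05). Tnf, the inflammatory cytokine, was higher by 1.02 ± 0.10 (95% interval 0.80 to 1.24, adjusted p = 3.05e-04).

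Genes lower with MI-503 included Gem and Foxp3. Gem was at 136 ± 18.6 with MI-463 and 46.7 ± 8.80 with MI-503 (SD, n = 3, log2 -1.52 ± 0.15, adjusted p = 2.14e-04, 95% interval -1.84 to -1.21). Foxp3, the factor of regulatory T cells, was at 205 ± 15.09 and 71.3 ± 12.98 (SD, n = 3, log2 -1.52 ± 0.19, adjusted p = 0.00212, 95% interval -1.93 to -1.11). Olfm4, a granule protein gene of neutrophils (log2 -1.22 ± 0.12, adjusted p = 2.14e-04, 95% interval -1.47 to -0.97), Il1rl1 (log2 -0.69 ± 0.090, adjusted p = 0.00268, 95% interval -0.88 to -0.49) and Chil3, with a close paralog (log2 -1.00017 ± 0.10, adjusted p = 3.05e-04, 95% interval -1.22 to -0.78), were lower too. These 9 genes passed whichever library was left out.

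Adamts9, a secreted protease gene, was lower with MI-503 (log2 -0.96 ± 0.15, adjusted p = 0.00933, 95% interval -1.28 to -0.64), as was Abcg1 (log2 -0.63 ± 0.092, adjusted p = 0.00544, 95% interval -0.83 to -0.44). Zfp36 (log2 0.86 ± 0.13, adjusted p = 0.00544, 95% interval 0.59 to 1.14) and Fkbp11, a prolyl isomerase gene of the secretory pathway (log2 0.96 ± 0.15, adjusted p = 0.0116, 95% interval 0.63 to 1.29), were higher. Without MI-503 replicate 2 the adjusted p of these 4 genes was 0.0622, 0.0509, 0.0509 and 0.0509, and without MI-503 replicate 1 that of Fkbp11 was 0.0693. Etv5 was lower (log2 -0.51 ± 0.089, adjusted p = 0.0197, 95% interval -0.71 to -0.32), but not without MI-463 replicate 2 (adjusted p = 0.0812), MI-503 replicate 1 (0.0806) or MI-503 replicate 2 (0.0958).

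Tnf and Tspoap1 moved in opposite directions under the compounds and differed between them in all leave-one-out fits. Tnf stood at 999.9 ± 122 with DMSO, fell to 756 ± 52.0 with MI-463 (log2 -0.40 ± 0.10, adjusted p = 0.00797) and rose to 1534 ± 134 with MI-503 (SD, n = 3, log2 0.62 ± 0.10, adjusted p = 3.26e-04). Tspoap1 went from 271 ± 37.1 to 181 ± 11.4 (log2 -0.57 ± 0.13, adjusted p = 0.00279) and 512 ± 68.5 (log2 0.92 ± 0.13, adjusted p = 6.74e-05).

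Elane, which encodes neutrophil elastase, was at 311 ± 53.2 with DMSO, 388 ± 11.7 with MI-463 (log2 0.33 ± 0.12, adjusted p = 0.0384) and 249 ± 9.14 with MI-503 (SD, n = 3, log2 -0.31 ± 0.12, adjusted p = 0.0475). The difference between the compounds passed (log2 -0.64 ± 0.12, adjusted p = 0.0262, 95% interval -0.89 to -0.39), but not without MI-463 replicate 1 (adjusted p = 0.0608), 2 (0.0747) or 3 (0.0639) or MI-503 replicate 1 (0.142) or 2 (0.104). Against DMSO, MI-463 passed only with all libraries or without DMSO replicate 3, MI-503 replicate 1 or MI-503 replicate 3. Its adjusted p was 0.155 and 0.120 without DMSO replicates 1 and 2, 0.0729, 0.0834 and 0.0657 without MI-463 replicates 1, 2 and 3, and 0.0523 without MI-503 replicate 2. MI-503 against DMSO passed only with all libraries or without DMSO replicate 1 or MI-463 replicate 1. Its adjusted p was 0.0611 and 0.219 without DMSO replicates 2 and 3, 0.0599 and 0.0616 without MI-463 replicates 2 and 3, and 0.135, 0.0852 and 0.0734 without MI-503 replicates 1, 2 and 3.

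As lists, 3 differed between the compounds also with an estimated correlation, all lower with MI-503. Mast cell and basophil genes were lower (median log2 -0.27, camera adjusted p = 4.96e-07, adjusted p = 0.0478 with an estimated correlation, 0 and 6 when adjusted over the list alone). Stem and progenitor genes (median log2 -0.15, camera adjusted p = 3.94e-04, adjusted p = 0.0478 with an estimated correlation, 0 and 7 when adjusted over the list alone) and DNA replication genes (median log2 -0.21, camera adjusted p = 7.13e-09, adjusted p = 0.0478 with an estimated correlation, 0 and 8 when adjusted over the list alone) were lower as well. Over all genes, 2 mast cell and basophil genes passed as lower, 1 without DMSO replicate 2, DMSO replicate 3 or MI-503 replicate 3, and 0 without MI-463 replicate 2 or 3 or MI-503 replicate 1 or 2. In the stem and progenitor list 1 gene passed as lower, and 0 without MI-463 replicate 2 or 3 or any 1 of the MI-503 libraries. That gene, Kit, is also 1 of the 2 mast cell and basophil genes. Kit had risen against DMSO under MI-463, so lower here does not mean a deeper fall. For the DNA replication genes the 1 that passed became 0 without DMSO replicate 1 or 2, any 1 of the MI-463 libraries, or MI-503 replicate 1 or 2.

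With the preset correlation alone, 7 more lists passed. Mitotic genes were lower with MI-503 (median log2 -0.24, camera adjusted p = 5.54e-10, adjusted p = 0.0601 with an estimated correlation, 0 and 10 when adjusted over the list alone). Over all genes 2 of them passed as lower, 1 without DMSO replicate 3 or MI-463 replicate 3, and 0 without DMSO replicate 1 or 2, MI-463 replicate 1 or 2, or MI-503 replicate 1 or 2. Immediate early and heat shock genes were higher (median log2 0.25, camera adjusted p = 3.92e-05, adjusted p = 0.163 with an estimated correlation, 11 and 3 when adjusted over the list alone). Over all genes 5 passed as higher, 3 without MI-463 replicate 1 or 3 or MI-503 replicate 1, and 2 without MI-503 replicate 2. Monocyte and macrophage genes were higher (median log2 0.079, camera adjusted p = 0.00734, adjusted p = 0.328 with an estimated correlation, 2 and 0 when adjusted over the list alone). Over all genes 1 passed as higher, and 0 without MI-463 replicate 1 or 2 or any 1 of the MI-503 libraries. Integrated stress response genes were higher (median log2 0.13, camera adjusted p = 3.94e-04, adjusted p = 0.3004 with an estimated correlation, 2 and 0 when adjusted over the list alone), with 0 past limma over all genes but 1 without MI-503 replicate 3. Interferon-stimulated genes were higher (median log2 0.13, camera adjusted p = 0.00679, adjusted p = 0.3004 with an estimated correlation, 2 and 0 when adjusted over the list alone), but not without MI-463 replicate 2 (camera adjusted p = 0.108). Their 1 gene past the test over all genes became 0 without DMSO replicate 2, any 1 of the MI-463 libraries or any 1 of the MI-503 libraries. Cholesterol synthesis genes were lower (median log2 -0.11, camera adjusted p = 0.0168, adjusted p = 0.3004 with an estimated correlation, 1 and 4 when adjusted over the list alone), but not without MI-463 replicate 2 (camera adjusted p = 0.0860) or MI-503 replicate 2 (0.0631). LXR and lipid export genes were lower (median log2 -0.083, camera adjusted p = 0.0271, adjusted p = 0.3004 with an estimated correlation, 0 and 2 when adjusted over the list alone), but not without MI-463 replicate 2 (0.109), MI-463 replicate 3 (0.0657) or MI-503 replicate 3 (0.110), nor without a filter (0.0579). In that list 1 gene passed over all genes, 2 without DMSO replicate 1 and 0 without MI-503 replicate 2.

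The other 17 lists did not pass between the compounds, which does not show that the compounds act alike on them. Of these, late granulocyte genes passed without MI-503 replicate 2 (camera adjusted p = 0.0441), and lysosome and cytokine signalling genes without MI-503 replicate 3 (0.0317 and 0.0407). With a filter at a mean of 50, menin-MLL1 target genes passed as lower with MI-503 (camera adjusted p = 0.0314) and cytokine signalling genes as higher (0.0451). Cytokine signalling genes also passed without both MI-463 replicate 1 and MI-503 replicate 3 (camera adjusted p = 0.0406), a setting added after the data were seen. Kmt2a (log2 -0.021 ± 0.12, adjusted p = 0.936, 95% interval -0.27 to 0.23), Men1 (log2 0.14 ± 0.091, adjusted p = 0.439, 95% interval -0.055 to 0.34), Cebpa (log2 0.28 ± 0.089, adjusted p = 0.169, 95% interval 0.094 to 0.48) and Meis1 (log2 -0.11 ± 0.11, adjusted p = 0.616, 95% interval -0.34 to 0.13) did not pass.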

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

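The tests of a lower share of mast-like and basophil-like cells and of the read total of MI-463 replicate 1 were chosen after the result was seen. Tnf, Elane and Tspoap1 stood out because both compounds moved each of them past the test in opposite directions. The effect of MI-503 minus that of MI-463 was 1.02 (log2) for Tnf, -0.64 for Elane and 1.49 for Tspoap1. Regrouping the 6 libraries of a comparison in the 10 possible ways gave as many called genes in 1 of 10, the real grouping, in each comparison. The real groupings called 4508, 4878 and 78 genes with limma and the highest of the others 0. However, 10 splits are too few for a share under 0.05. Each other split also mixes the compared treatments, so a real difference widens the spread and lowers the calls. The 0 is thus no measure of chance.

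Mast cell and basophil genes fell while monocyte and late granulocyte genes rose under both compounds. Over TMM scaling, quantile normalization, edgeR (also with TMM factors) and DESeq2 and both compounds, the smallest list median in its own direction was 0.505 (log2). That argues against library size or the choice among these scalings. All of them assume that most genes, or the spread of all values, stayed the same. A shift of all genes together would thus stay hidden. Such a shift would move every list alike and leave the gap between falling and rising lists. A lower share of mast-like and basophil-like cells with no other change would raise markers of every other type alike. Monocyte genes rose above the 24 eosinophil, erythroid, megakaryocyte and stromal genes by 1.10 with MI-463 (95% bootstrap interval 0.324 to 1.49). With MI-503 the difference was 1.36 (0.564 to 1.83). Whether mast-like or basophil-like cells express some of those 24 genes was not tested, and such genes would fall with them. The bootstrap also drew genes as if independent, so its intervals may be too narrow. The comparison thus cannot exclude a lower share of mast-like and basophil-like cells. That lower share, a shift toward monocyte-like and granulocyte-like expression or growth of such cells may underlie the pattern. These data do not separate those.

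MI-463 replicate 1 lay apart from replicates 2 and 3. MI-503 replicate 3 also lay apart from its group, and the deviations of these libraries correlated at 0.471. The pattern was not limited to them. With MI-463 replicate 1 and MI-503 replicate 3, the deviations of DMSO replicate 1 correlated at 0.284 and 0.384. Those of DMSO replicate 2 correlated at 0.146 and 0.0651, and those of DMSO replicate 3 at -0.3999 and -0.423. The DMSO libraries thus varied in part along the same direction. The main fit has no term for it, and its source was not tested. The read total of MI-463 replicate 1, 14.4 megareads, lay inside the range of the other MI-463 libraries (13.88 to 14.45), which argues against sequencing depth. The median deviation of mitotic and DNA replication genes together in MI-463 replicate 1 was 0.00268 (log2). A size under 0.1 was set in advance to argue against a different share of dividing cells, and this value met that limit. The lists went opposite ways (0.111 and -0.038), however, which the limit did not foresee, so the joint value decides nothing. Mitotic genes deviated about as far in DMSO replicate 1 (0.111) and MI-503 replicate 3 (0.135). Without MI-463 replicate 1, 15 rather than 9 mitotic genes fell under MI-463. A different share of dividing cells thus stays open. The deviation correlated with the genomic span of genes at rho = 0.271, between the 0.1 set for no length bias and the 0.3 set for such bias. MI-463 replicate 3 had rho = -0.304, in part forced, since deviations within a group sum to 0. Among the MI-503 libraries replicate 2 had rho = -0.229. MI-503 replicate 3, which also lay apart, had rho = 0.0905, under the 0.1 set for no length bias. Length bias cannot be told apart from other sources, and the middle value of MI-463 replicate 1 keeps it open.

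For the 78 genes called between MI-503 and MI-463, a greater depth of the MI-503 libraries was tested by thinning them to 14,168,342 reads, and 74 of the 78 remained called, which argues against it. A stronger form of the shared response under MI-503 would move the genes along their mean response, and 69.2% of them (54 of 78) did so. That lies between the 65% and 80% set in advance. It held for 28 of 34 genes with a falling mean response but 26 of 44 with a rising one. Over all genes the slope of MI-503 on MI-463, corrected for error, was 1.01. The slope of the difference between the compounds on their mean response was 0.060, slightly toward a larger response under MI-503. No spread was computed for either slope, so they do not settle whether the responses were equally strong. From the share alone a stronger form cannot be told apart from effects of each compound alone. Without MI-463 replicate 1, 47 of the 78 genes remained called, between 50% and 80%. Fewer remained without MI-463 replicate 2 (31) or 3 (43) or MI-503 replicate 1 (26) or 2 (16), and 61 without MI-503 replicate 3, so the loss was no sign of a particular part of MI-463 replicate 1. By the limits set in advance the share decides nothing, but the 47 genes still called without MI-463 replicate 1 do not rest on it alone. For the remaining genes the part of MI-463 replicate 1 stays undecided.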

How the results depend on the processing

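The counts of genes called against DMSO (4508 with MI-463, 4878 with MI-503, 3557 with both) stayed within 1.5 times in all settings except a fold change of at least 2 (788, 891 and 646). The count between MI-503 and MI-463, 78, was less firm: 43 with the 2 compared groups alone, 40 without trend, 453 with sample weights, 258 with DESeq2, 12 at a fold change of at least 2, and 16 (without MI-503 replicate 2) to 89 (without MI-503 replicate 3) with 1 library left out. It was 26 without MI-503 replicate 1, 33 without MI-463 replicate 2 and 50 without MI-463 replicate 1. The cause was not tested, apart from the stricter threshold, which removes genes by construction. Kmt2a under MI-463 (log2 0.34) lost its call without trend (adjusted p = 0.0688) and had 0.22 to 0.41 with 1 library left out. Kmt2a under MI-503 (0.32) lost it without a filter (adjusted p = 0.0532) and without trend (0.0811), and had 0.20 to 0.40 with 1 library left out. Between the compounds Kmt2a (-0.021) changed sign, to 0.078 with sample weights, to 0.058 without MI-463 replicate 1 and to 0.060 without MI-503 replicate 3, and with 1 library left out had -0.0997 to 0.060. The setting chosen after the data were seen, leaving out both MI-463 replicate 1 and MI-503 replicate 3, gave Kmt2a 0.26 under MI-463 (adjusted p = 0.0524) and 0.14 between the compounds. Of the lists, 13, 17 and 10 passed camera with the preset correlation. With an estimated correlation 8, 7 and 3 passed, with fry 20, 21 and 8, and with fry in either direction 27, 27 and 19. The fry test asks whether the members changed at all, while camera asks whether they changed more than other genes. With 39.7% and 42.9% of all genes called against DMSO, nearly any list would pass fry in either direction. The fry counts are thus no check of the camera calls.

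Replicate numbers were also tried as a block, although they do not pair the samples: deviations of libraries with the same number correlated at -0.423 to 0.284. The block gave 49 genes between the compounds, and Kmt2a missed the threshold under MI-463 (log2 0.34, adjusted p = 0.0525) and MI-503 (0.32, 0.0632).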

Other observations

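The list of NRF2 targets was chosen after the result was seen, and its test is the one of this part. Under both compounds Slc7a11, Osgin1 and Hmox1, all known targets of the transcription factor NRF2, rose together. Osgin1, a stress-induced growth inhibitor gene, went from 326 ± 63.0 with DMSO to 1936 ± 149.7 with MI-463 (log2 2.58 ± 0.15, adjusted p = 2.55e-08) and 2084 ± 363 with MI-503 (SD, n = 3, log2 2.67 ± 0.15, adjusted p = 1.57e-08). Hmox1, heme oxygenase 1, went from 1223 ± 141 to 6305 ± 669 (log2 2.37 ± 0.13, adjusted p = 1.79e-08) and 6906 ± 1351 (log2 2.49 ± 0.13, adjusted p = 9.99e-09). Ifi47, an interferon-induced GTPase gene, fell (log2 -2.06 ± 0.099, adjusted p = 5.66e-09 with MI-463 and log2 -2.04 ± 0.099, adjusted p = 5.03e-09 with MI-503) while most interferon-stimulated genes rose.

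A candidate explanation is a wider NRF2 response. Of 26 other listed targets, none of which the other lists hold, 24 were tested and 15 rose with MI-463 and 16 with MI-503, with 0 past limma as lower. The lower of the medians was 0.365 (log2). Camera of limma, BH-adjusted over the 3 comparisons, gave adjusted p = 2.33e-06 with MI-463 and adjusted p = 1.86e-06 with MI-503 at the preset correlation, and adjusted p = 0.00432 for both at an estimated one. Between the compounds limma camera gave adjusted p = 0.0934. Because the pattern was noticed and tested in the same data, it is a hypothesis, and oxidative stress, a direct effect of the compounds or a change of cell type may each underlie it.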
